A study of Homo sapiens with 6 samples.

How the data were processed

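Gene expression was measured in LNCaP cells, an androgen-responsive line established from a human prostate cancer metastasis, on 6 single-colour Agilent arrays that shared 1 slide. Per the labels, cells were kept in medium with 10% fetal bovine serum (FBS), for 5 days in medium with 5% dextran-coated charcoal-stripped serum (DCC), from which steroids had been removed, or in the stripped medium followed by 16 h with 10 nM R1881, a synthetic androgen. Each of the 3 groups held 2 arrays.

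Per the file headers, the scanner images were read with Agilent Feature Extraction 11.0.1.1, while the submitters' processing notes name version 9.1. The deposited scanner values are Cy3 spot intensity on a linear scale. Per the file headers, the processed intensity was background-subtracted and detrended within each array, and it was not normalised between arrays. The authors' value table holds log2 values. Its scale was found by setting its columns against the scanner values of all 42405 probes: each column correlated with 1 scan at 0.99906 or more, the 6 sorted columns differed by at most 0.000774, and every column had a median of 6.414, so the authors' log2 values were quantile-normalised between arrays and rise with the intensity. How the authors made that table beyond this is not given in the sources used here. All value columns were matched to a sample by name.

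For the comparisons, log2 of the processed intensity was taken and each array's own 75th percentile subtracted, so that every level and change is relative to that percentile. Control spots and spots marked as outliers were left out before the spots of a probe were averaged, which left 16 probes without a value on at least 1 array and out of the tests; 0 spots were saturated. Probes well above background on at least 2 of the 6 arrays were kept (29044 probes), and for each gene the probe with the highest mean over the 6 arrays was used. Accessions were matched without versions to the RefSeq genes of GRCh38.p14, used only for names: 26364 probes matched a gene. Of the 23683 genes or transcripts tested, 15141 had a reference symbol and 8542 kept the array design's identifier. For the genes selected by the rule below, other probes that differed from the one used by more than 1.5-fold are given beside it.

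Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), over all 6 arrays with the group as a factor, since 2 arrays a group leave 3 residual degrees of freedom only when the groups share 1 estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 were counted as higher or lower. Fold changes are given with the standard error (SE) of the log2 change, and group means with the SD over 2 arrays. An exact permutation test of 2 arrays against 2 cannot give a two-sided p under 0.333, so none was used. Where a probe was not well above background on any array of a group, the fold is a bound: the mean log2 level of the brighter group against the dimmer group's mean of, for each array, the higher of the lowest level among probes well above background and the probe's own level. Such folds are written as at least N-fold.

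Gene lists, 31 in all, were written before the data were examined. They covered androgen-induced and androgen-repressed genes, proliferation and replication, lipid, sterol, polyamine, glucose and steroid metabolism, secretion, glycosylation and stress responses, inflammatory and interferon genes, apoptosis and p53 targets, receptors and coregulators, growth factor, WNT and BMP signalling, ribosomes, oxidative phosphorylation, developmental factors, and markers of luminal, neuroendocrine, mesenchymal, basal, fibroblast and leukocyte cells. Each list was tested against all other genes with camera at a preset correlation of 0.01, two-sided, adjusted over the 31 lists of a comparison. The same test with a correlation estimated from the arrays, and fry, were alternatives. With an estimated correlation, camera refers its statistic to the 3 residual degrees of freedom, so few lists can pass. Calls lost there cannot be put down to correlation between genes alone. Members past the threshold were counted with p adjusted over all genes and adjusted over the list alone.

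The genes named in the text were chosen by a rule fixed at the same time: 6 label check genes in every comparison, among them KLK3, KLK2, TMPRSS2 and FKBP5, then the 12 largest rises and 12 largest falls by log2 fold change (5 each way for R1881 against FBS) among genes past the threshold whose groups did not overlap, with an official symbol and a probe well above background on all arrays of the higher group. In each list, up to 4 members with the largest change were eligible, or 2 where none passed. Members that went against the rest of a list are named as well, and these were chosen after their values were seen. 6 genes that the rule selected are not reported here.

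For 2 arrays the description field contradicts the title, source name and treatment. The plan, fixed with the lists, grouped arrays by title, with grouping by description and leaving out both arrays as alternatives. The rule for named genes was applied unchanged to both groupings. Grouping by description was chosen for the detailed account only after the androgen-regulated genes and the match between scans and value table had been seen.

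Further alternatives were normexp background correction (offset 50), run on the median spot and background intensities, since the files used here hold no mean intensity, so that it changed the intensity as well as the background step; quantile normalisation; no filter, or a filter on all 6 arrays; every probe kept, or a gene's probes averaged; the authors' value table, in which the normalisation and the columns of 2 scans both differ; eBayes with trend and robust options; only the groups compared; the replicate number or the slide row as a block; a fold change of at least 1 on the log2 scale; and each array left out in turn. The number of arrays limits the precision. Leaving out both arrays with contradictory labels left 1 array each in DCC and R1881, so the spread came from the FBS pair alone. Each array left out in turn left 1 array in its group, and the spread came from the other groups. The procedure was tested on simulated data for R1881 against DCC with 200 of 23683 genes changed. It called 9% of 67 genes changed 1.5-fold, 65.7% of 67 changed 2-fold and 92.4% of 66 changed 4-fold, all in the right direction, and 7 of its 118 calls were genes left unchanged. A list of 25 genes shifted by 1 on the log2 scale was called among 31 lists, with 0 calls among the rest. The simulated noise was independent between genes, so the list test was not tried on correlated genes. With 200 genes changed, these rates need not hold where many more genes were called, as in the real comparison.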

Results

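Transcript levels were measured in LNCaP prostate cancer cells in steroid-containing medium (FBS), after 5 days in steroid-depleted medium (DCC), and in depleted medium with 10 nM R1881 for the last 16 h, with 2 arrays in each group. The comparisons address how LNCaP cells responded to the withdrawal of steroids and to the return of an androgen. Arrays of the FBS group had 65.2% and 67.5% of probes well above background, those described as DCC 62.1% and 59.9%, and those described as R1881 66.5% and 64.7%. The 75th percentile of the processed intensity was 1132 and 1194 in FBS, 993.2 and 862.8 in DCC, and 1162 and 1163 in R1881. Across genes, which are not independent replicates, the paired arrays of a group by description correlated at 0.9958 (FBS), 0.9902 (DCC) and 0.9952 (R1881), and arrays of different groups at 0.9461 to 0.9646. Nothing in the labels says that the 2 arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

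The androgen-regulated genes set for a check of the labels split the arrays by their description and not by their title. KLK3, which encodes prostate-specific antigen, had log2 levels of 7.99 and 7.89 in FBS, 3.85 in the array titled R1881 1 but described as DCC, and 3.67 in DCC 2. In the array titled DCC 1 but described as R1881, KLK3 was at 7.90, close to the 7.83 of R1881 2. FKBP5, a steroid-induced gene that encodes a co-chaperone of HSP90, was at -2.24 in the array titled R1881 1 and 3.61 in the array titled DCC 1, against 3.65 in R1881 2 and -2.11 in DCC 2. The 26 canonical androgen-induced genes had a median difference of -3.71 between the array titled R1881 1 and the array titled DCC 1, with 1 gene higher in the former. Between R1881 2 and DCC 2 the median difference was 3.65, with 25 of 26 genes higher in R1881 2. Each of these 2 scans correlated best with the other record's column of the authors' value table, at 0.99991 and 0.9995, against 0.96565 and 0.9644 with its own column. The other 4 scans matched their own columns at 0.99906 or more. The scans thus went with the description, while the value table went with the title, and both routes give each scan the same group.

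**Figure D1:**
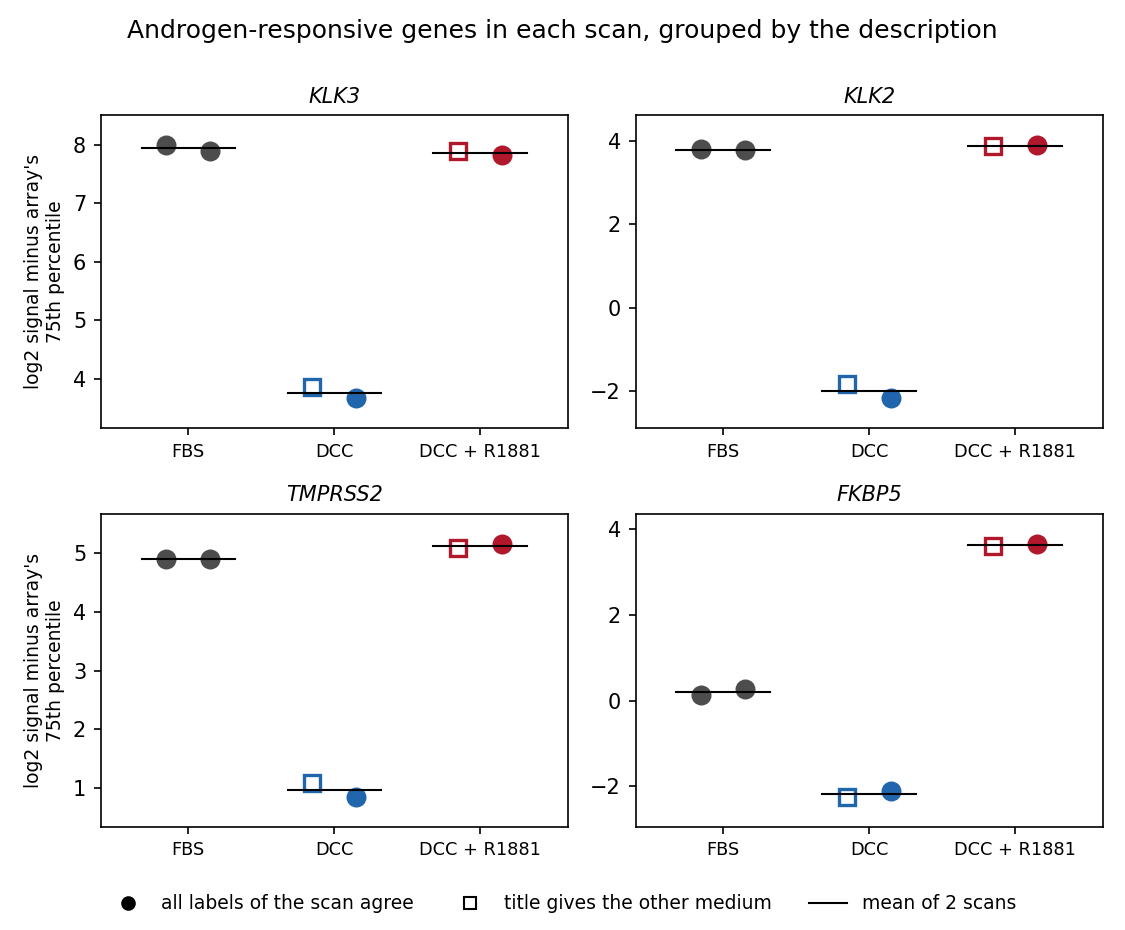
Log2 processed intensity minus the array's 75th percentile for 4 androgen-responsive genes, 1 point per scan, grouped by the description, with open squares for the 2 scans whose title names the other medium and lines for the mean of 2 scans. KLK3 was at 3.85 and 3.67 in the DCC scans and at 7.90 and 7.83 in the R1881 scans.

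By title, the DCC and R1881 groups each held 1 scan described as DCC and 1 described as R1881, so neither group gives 1 medium alone. Grouped by title, as planned, UGT2B11, a glucuronosyltransferase of the androgen-inactivating family, was 108-fold higher in DCC than in FBS (log2 change 6.75 ± 0.24 SE, adjusted p = 0.0428) and 103-fold higher in R1881 than in FBS (6.68 ± 0.24, adjusted p = 0.0448). ID3, an inhibitor of basic helix-loop-helix factors, rose by 3.46 on the log2 scale and CD24, a surface glycoprotein, by 3.32 in DCC against FBS. NTN4, a netrin, was at least 12.1-fold higher, and TMSB4X, ENTPD8, CYP1A1, OPTN, FOSL2 and JMJD1C-AS1 rose by 2.29 to 3.08 on the log2 scale. H3C15 and H3C2, replication-dependent histone H3 genes, were 43.6-fold and 7.34-fold lower in DCC, though near-identical H3 copies make their probes uncertain. ADARB2 was 28.3-fold lower by the probe used, which was above background on 1 of 2 DCC arrays, and its other probes gave log2 changes of -2.44 and -1.51. RBM24 was 13.0-fold and FOXN4 9.62-fold lower, and so were CDC45 (8.32-fold), a DNA replication gene, BLM (7.35-fold), a DNA helicase, KIF24 (7.08-fold) and E2F2 (6.89-fold), a cell cycle transcription factor. NEIL3, a DNA glycosylase, was at least 8.23-fold and DAPL1 at least 7.42-fold lower. Each of these falls and the rises other than UGT2B11 had an adjusted p of 0.046. KLK3 had no call between R1881 and DCC by title, with a log2 change of 0.06 ± 1.89 SE.

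Counts by title were 10 genes higher and 20 lower in DCC than in FBS, and 1 higher (UGT2B11) and 0 lower in R1881 than in FBS. Between R1881 and DCC limma called 0 genes, with 222 at an unadjusted p under 0.05, and 0 with the trend and robust options, with 86 at an unadjusted p under 0.05. Leaving out any 1 array left 0 calls in all 3 comparisons. In DCC against FBS, by title, 1 of 36 mitosis genes fell and 35 fell adjusted over the list alone (median log2 change -2.07, camera adjusted p = 1.44e-21, and adjusted p = 0.736 with an estimated correlation). Of 44 DNA replication genes 3 fell, 41 adjusted over the list alone (median -1.65, camera adjusted p = 1.56e-29, and adjusted p = 0.128 with an estimated correlation). Ribosome biogenesis genes fell as a list (20 of 23 adjusted over the list alone, camera adjusted p = 2.61e-11, and adjusted p = 0.128 with an estimated correlation). These 3 lists also fell in R1881 against FBS (camera adjusted p = 2.76e-24, 4.24e-34 and 1.03e-12, and adjusted p = 0.602, 0.104 and 0.104 with an estimated correlation). In DCC against FBS the broad androgen response, interferon, NF-kB and WNT and BMP lists rose and ribosomal proteins fell (camera adjusted p = 0.0186, 0.00788, 0.0186, 0.00036 and 0.00036, and adjusted p = 0.949, 0.736, 0.736, 0.332 and 0.736 with an estimated correlation). In R1881 against FBS interferon, NF-kB and WNT and BMP lists rose and ribosomal proteins fell (camera adjusted p = 0.00152, 0.0298, 0.000553 and 2.3e-05, and adjusted p = 0.774, 0.774, 0.36 and 0.774 with an estimated correlation). No list passed between R1881 and DCC. Both of these title groups mixed the descriptions, and by description the broad androgen response fell in DCC against FBS. The prior spread of a gene was 0.246 on the log2 scale by title and 0.108 by description. From here on, group and array names follow the description, a fixed alternative that was chosen for the detailed account after the label check had been seen.

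Grouped by description, the classical androgen targets were higher with R1881 in steroid-depleted LNCaP cells. The label check genes and the canonical androgen-induced list were seen before this grouping was chosen. The broad androgen response shares genes with that list, among them HPGD, KLK2 and FKBP5. The p-values of the label check genes and of both lists, in each comparison, are therefore no independent check of this grouping. KLK3 was 17.2-fold higher with R1881 than in DCC (log2 change 4.11 ± 0.10 SE, adjusted p = 3.98e-05), at a mean of 7.86 ± 0.05 (SD, n = 2) against 3.76 ± 0.13. KLK2, a neighbouring kallikrein, was 58.8-fold higher (5.88 ± 0.13, other probe 6.34), FKBP5 55.8-fold (5.80 ± 0.09), and TMPRSS2, a membrane serine protease, 17.9-fold (4.16 ± 0.10).

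The largest rises with R1881 reached genes outside the prostate kallikreins. KRT6B, a stress and wound keratin, rose by a log2 change of 10.72 ± 0.57, but it was above background on 1 of 2 DCC arrays, and the change was 9.84 without DCC 1 and 11.61 without DCC 2. KRT6C was at least 215-fold higher. Probes of the KRT6 genes and of ORM1 and ORM2 may detect their close paralogs. ORM1 and ORM2, which encode acute-phase plasma glycoproteins, were 120-fold and at least 262-fold higher. ANGPT2, a vascular ligand of the TIE2 receptor, was 230-fold higher (7.85 ± 0.32), ST6GALNAC1, a sialyltransferase that makes the sialyl-Tn antigen, 194-fold (7.60 ± 0.19), and S100P, a calcium-binding protein, 152-fold (7.25 ± 0.09). PTCRA was at least 200-fold, HPGD, the prostaglandin-degrading dehydrogenase, at least 135-fold, EMP1, an epithelial membrane protein, at least 126-fold and MMP12, a metalloelastase, at least 82.9-fold higher, and TRIM53AP, a pseudogene above background on 1 of 2 DCC arrays, rose by 6.99 (5.75 without DCC 1, 8.23 without DCC 2, other probes 4.59 and 5.68). OPRK1, the kappa opioid receptor, was 301-fold lower (-8.24 ± 0.10) and DDC, which makes dopamine and serotonin from their amino acid precursors, 209-fold lower (-7.71 ± 0.08). SLITRK3 was at least 133-fold lower, GRIK1, a kainate receptor subunit, at least 88.6-fold, MMP16 at least 75.1-fold, AMIGO2 at least 65.5-fold, SI at least 57.3-fold and NRG3, a neuregulin, at least 46.5-fold (log2 change -6.78, other probe -5.26). UGT2B15, which glucuronidates androgens, was 60.3-fold, BCHE, butyrylcholinesterase, 59.5-fold and TENM2, a teneurin, 59.3-fold lower. Adjusted p-values of the genes in this paragraph lay between 2.05e-05 and 0.00203.

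Androgen-regulated lists moved in opposite directions. Of the 26 canonical androgen-induced genes, 25 rose and 1 fell with R1881, the metalloreductase gene STEAP2 (-0.81) (median log2 change 3.68, camera adjusted p = 8.02e-16, and adjusted p = 0.0932 with an estimated correlation). Within the broad androgen response of 101 genes, 87 rose and 3 fell, and 88 rose adjusted over the list alone (median 1.86, camera adjusted p = 1.02e-27), with HPGD, KLK2, FKBP5 and STEAP4 (at least 23.5-fold, log2 change 5.21, other probe 7.25) the largest. That list alone kept its call in this comparison when the correlation was estimated (adjusted p = 0.0169). Among 13 measured androgen-repressed genes 12 fell, led by OPRK1, UGT2B15, BCHE and CAMK2N1 (42.9-fold lower), and 0 rose (median -3.09, camera adjusted p = 3.68e-07, and adjusted p = 0.156 with an estimated correlation). Of 22 steroid receptors and their coregulators 17 fell and 3 rose, 4 adjusted over the list alone (median -0.79, camera adjusted p = 0.00102, and adjusted p = 0.148 with an estimated correlation). GATA2, a zinc finger transcription factor, was 5.63-fold, NR3C2, the mineralocorticoid receptor, 4.88-fold and TLE3, a corepressor, 3.45-fold lower. Lists given without a second count had the same count adjusted over the list alone, here and in the paragraphs that follow.

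Lipid, secretory and glycosylation genes rose with R1881. In cholesterol synthesis and uptake 22 of 24 genes rose and 2 fell, TM7SF2 and HSD17B7 (median log2 change 1.31, camera adjusted p = 1.95e-10, and adjusted p = 0.0932 with an estimated correlation). INSIG1, a feedback regulator of sterol synthesis, was 5.64-fold and HMGCS1, HMG-CoA synthase, 5.59-fold higher. In fatty acid synthesis 16 of 18 rose and 2 fell, MLXIPL and GPAM (median 1.30, camera adjusted p = 3.68e-07, and adjusted p = 0.0932 with an estimated correlation), with ELOVL7, a fatty acid elongase, 16.0-fold and DBI, which binds acyl-CoA, 6.46-fold higher. Of 14 polyamine and prostate secretory genes 9 rose and 2 fell, OAZ2 and ACP3 (median 0.93, camera adjusted p = 0.00108, and adjusted p = 0.131 with an estimated correlation). MSMB, a secretory protein of prostate fluid, was 25.6-fold, SAT1, a polyamine acetyltransferase, 11.3-fold and SMS, spermine synthase, 9.13-fold higher, and SORD, sorbitol dehydrogenase, rose by 3.46. In the unfolded protein response and secretory pathway 25 of 32 rose and 0 fell (median 0.62, camera adjusted p = 5.08e-08, and adjusted p = 0.0932 with an estimated correlation), including SPCS3, a signal peptidase subunit (5.14-fold), and DNAJB9, an endoplasmic reticulum co-chaperone (3.37-fold). In protein glycosylation 22 of 24 rose, 23 adjusted over the list alone (median 0.81, camera adjusted p = 1.37e-09, and adjusted p = 0.131 with an estimated correlation), led by ST6GALNAC1 and PGM3 (6.76-fold) of the UDP-GlcNAc pathway, while STEAP1, which the list also held, fell.

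Mitosis and ribosomal protein genes went the other way. Of 36 mitosis genes 28 fell and 1 rose, CCNB1 (2.40-fold higher), with 30 falling adjusted over the list alone (median log2 change -0.81, camera adjusted p = 9.15e-07, and adjusted p = 0.365 with an estimated correlation). TOP2A, topoisomerase II alpha, was 2.66-fold and BUB1B, a spindle checkpoint kinase, 2.59-fold lower. Of 44 DNA replication genes 19 fell (20 adjusted over the list alone) and 4 rose, MCM5, GINS3, POLE2 and FEN1, and the list did not pass (median -0.22, camera adjusted p = 0.109), though CCNE2, cyclin E2, was 4.99-fold lower. Of 25 cytosolic ribosomal protein genes 21 fell, 22 adjusted over the list alone, RPL5 by 0.69 and RPL13 by 0.68 on the log2 scale among them (median -0.38, camera adjusted p = 7.71e-05, and adjusted p = 0.252 with an estimated correlation). Ribosome biogenesis was mixed, with 4 genes higher and 6 lower of 23 (camera adjusted p = 0.93), and MYC, a driver of that programme, was 2.02-fold lower. In oxidative phosphorylation 6 of 23 rose, NDUFV2 (0.93) and COX6C (0.60) the most, and 4 adjusted over the list alone (median 0.19, camera adjusted p = 0.0106, and adjusted p = 0.148 with an estimated correlation), a call lost with quantile normalisation (adjusted p = 0.617).

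Inflammatory and stress genes rose as well. Of 16 NF-kB and inflammatory genes 12 rose, 13 adjusted over the list alone, and 2 fell, NFKB1 and IL1B (median log2 change 1.92, camera adjusted p = 3.6e-05, and adjusted p = 0.0932 with an estimated correlation). CXCL10, a chemokine, was 81.3-fold higher and above background on 1 of 2 DCC arrays (SD 0.85 between them), TNF at least 16.7-fold and CCL2, a monocyte chemokine, at least 10.7-fold higher, while IL1B, interleukin 1 beta, was at least 33.4-fold lower. In the interferon response 15 of 26 rose and 1 fell, MX1, with 16 and 2 adjusted over the list alone (median 0.49, camera adjusted p = 3.6e-05, and adjusted p = 0.148 with an estimated correlation), OAS1 at least 5.32-fold and ISG20 4.58-fold among them. In heat shock and oxidative stress 12 of 20 rose and HSP90AA1 fell (median 0.57, camera adjusted p = 7.96e-05, and adjusted p = 0.131 with an estimated correlation), with HMOX1, heme oxygenase, 9.75-fold higher. Of 20 immediate early genes 11 rose, ATF3 11.7-fold (3.54, other probes from 0.34 to 3.57) and DUSP5 8.67-fold (above background on 1 of 2 DCC arrays), and JUN, DUSP6 and MYC fell (median 0.61, camera adjusted p = 0.0069, and adjusted p = 0.271 with an estimated correlation). The p53 targets and cell cycle inhibitors split, with 8 higher and 8 lower of 20, 9 lower adjusted over the list alone (median -0.05 but mean 0.23 and test direction up, camera adjusted p = 0.657), CDKN2B, an inhibitor of CDK4 above background on 1 of 2 DCC arrays, 11.5-fold higher and SESN1 4.93-fold lower. Of 18 apoptosis regulators 7 were higher and 4 lower (median 0.03, and -0.05 with normexp or quantile normalisation, camera adjusted p = 0.423), BIRC3 10.7-fold higher and BMF, a BH3-only factor, 6.06-fold lower (-2.60, other probe -1.59).

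In metabolism and signalling, 13 of 22 glycolysis genes rose and 2 fell, PFKM and ENO2 (median log2 change 0.45, camera adjusted p = 0.00644, and adjusted p = 0.363 with an estimated correlation), with PFKFB2, which raises fructose 2,6-bisphosphate, 8.10-fold higher. In steroid metabolism 9 of 17 measured genes rose, 10 adjusted over the list alone, and UGT2B15 and AKR1C3 fell (median 0.68, camera adjusted p = 0.00712, and adjusted p = 0.219 with an estimated correlation). CYP1B1 was at least 7.31-fold and HSD17B11 6.42-fold higher. Growth factor and PI3K genes were 9 higher, 10 adjusted over the list alone, and 6 lower of 18 (median 0.40, camera adjusted p = 0.0622, and 0.0123 with normexp or 0.0373 without DCC 2), INPP4B, a phosphatase that opposes PI3K, at least 12.6-fold, IGFBP3 9.13-fold and IGF1R 7.64-fold higher. WNT and BMP genes were 4 higher and 7 lower of 17 (median -0.29, camera adjusted p = 0.489), FZD5, a WNT receptor, 17.4-fold higher and ID1 5.85-fold lower. HOX and neural crest factors were 1 higher, SOX9, and 5 lower of 8 (median -0.57, camera adjusted p = 0.0638, and 0.0296 with quantile normalisation and 0.0427 to 0.0475 without FBS 1, FBS 2, DCC 1 or R1881 2), HOXA13 at least 6.61-fold lower.

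Markers of cell types were measured beside these groups. Luminal markers rose in 11 of 18 and fell in 5, HOXB13, FOXA1, FOLH1, STEAP1 and ACP3 (median log2 change 0.81, camera adjusted p = 0.00567, and adjusted p = 0.363 with an estimated correlation), with KRT19 15.4-fold and KRT8 5.19-fold higher. Of 9 measured basal markers 5 rose and 1 fell, LAMB3, a laminin chain, 54.2-fold higher (median 0.70, camera adjusted p = 0.0383, and adjusted p = 0.363 with an estimated correlation). That call was lost with normexp (median -0.07, adjusted p = 0.0949) and without DCC 2 (0.0549). The 10 measured neuroendocrine markers had 0 higher and 3 lower, DDC, ENO2 and SNAP25 (median -0.69, camera adjusted p = 0.299). Epithelial-mesenchymal genes had 5 higher and 2 lower of 13, SNAI2 at least 15.2-fold higher and FN1 at least 7.57-fold lower (median 0.21, camera adjusted p = 0.0638, and 0.0234 with quantile normalisation or 0.0461 without either FBS array). CD68, a lysosomal protein used as a macrophage marker, was the 1 leukocyte marker of 9 that differed, 17.7-fold higher (median 0.19, and -0.04 with normexp, camera adjusted p = 0.205). Of 3 measured fibroblast markers ACTA2 was 3.95-fold higher and COL1A1 1.81-fold lower (median -0.65 but mean 0.16 and test direction up, camera adjusted p = 0.985).

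Across the 23683 genes or transcripts, limma called 4987 higher and 6344 lower with R1881 than in DCC, 47.8% of those tested, against 0 and 0 by title, and 1784 and 2017 of them changed at least 2-fold. Without the 2 arrays with contradictory labels, DCC and R1881 held 1 array each and only the FBS pair gave a spread, so no counts are given. Both DCC arrays lay in slide row 2 and the other 4 arrays in slide row 1, so slide row and medium cannot be told apart in comparisons with DCC, and 44.0% of the calls were higher, against 33.5% with normexp.

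**Figure D2:**
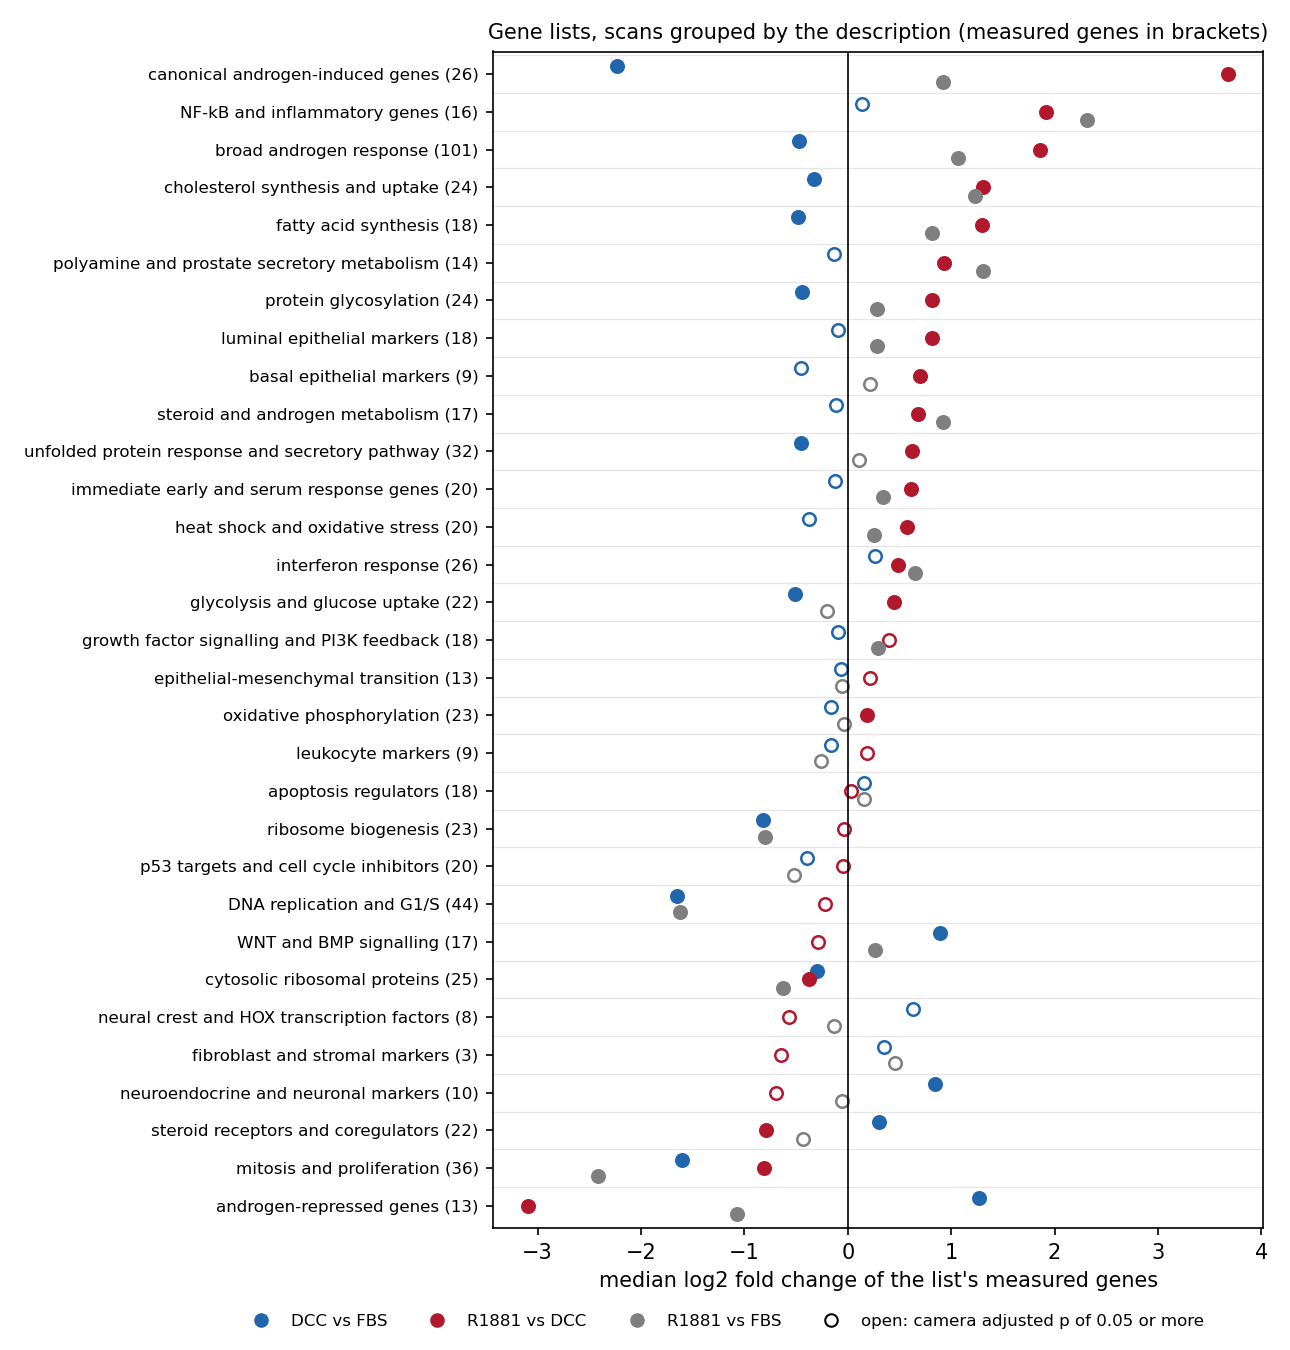
Median log2 fold change of the measured genes of 31 lists (numbers in brackets) in DCC against FBS, R1881 against DCC and R1881 against FBS, with filled points for lists with a camera adjusted p under 0.05. Canonical androgen-induced genes lay at -2.23, 3.68 and 0.92, and mitosis genes at -1.60, -0.81 and -2.42.

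In steroid-depleted medium the same androgen targets were low and androgen-repressed genes were high. KLK3 was 18.1-fold lower in DCC than in FBS (log2 change -4.18 ± 0.10 SE, adjusted p = 0.00015), at 3.76 ± 0.13 (SD, n = 2) against 7.94 ± 0.07. KLK2 was 55.0-fold (-5.78 ± 0.13, other probe -5.05), TMPRSS2 15.4-fold (-3.94 ± 0.10) and FKBP5 5.17-fold lower (-2.37 ± 0.09).

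OPRK1 was 150-fold (log2 change 7.23 ± 0.10) and UGT2B15 114-fold higher in DCC (6.84 ± 0.12). UGT2B11 was 93.6-fold and UGT2B10 43.8-fold higher, and probes of the UGT2B genes may detect one another's transcripts. GRIK1 was at least 88.3-fold, MID1, a ubiquitin ligase of microtubules, at least 38.4-fold, NRG3 at least 36.2-fold (5.18, other probe 4.31), IL1B at least 33.3-fold, DCDC2, a doublecortin-domain protein, at least 30.5-fold, BEND5 at least 29.5-fold and PNMA2 at least 24.9-fold higher, and TENM2 was 36.4-fold higher (5.19, other probe 6.37). S100P was 116-fold lower (-6.85 ± 0.09), KLK5 29.8-fold, PHGR1 31.1-fold and ANGPT2 26.1-fold. NPPC, a natriuretic peptide, was 42.5-fold lower and above background on 1 of 2 DCC arrays. H3C15 was 32.8-fold lower, ADARB2 at least 27.5-fold by the probe used (-4.78, other probes -3.58 and -2.48), PLOD2, a collagen lysyl hydroxylase, at least 16.9-fold, TBX15 at least 14.3-fold and LCN2, lipocalin 2, at least 12.9-fold. Adjusted p-values of the genes in this paragraph lay between 0.000101 and 0.00403.

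Of the 26 canonical androgen-induced genes 25 fell in DCC and STEAP2 rose (0.37) (median log2 change -2.23, camera adjusted p = 7.85e-12, and adjusted p = 0.193 with an estimated correlation). The broad androgen response had 64 genes lower, 67 adjusted over the list alone, and 12 higher of 101 (median -0.47, camera adjusted p = 7.21e-08, and adjusted p = 0.0715 with an estimated correlation), among the lowest MAK, a kinase (at least 17.0-fold). Of 13 androgen-repressed genes 9 rose and 4 fell, MYC, HSD17B6, TYMS and PEG3 (median 1.27, camera adjusted p = 0.00889, and adjusted p = 0.364 with an estimated correlation), MET, the hepatocyte growth factor receptor, at least 10.4-fold and BCHE 8.55-fold higher. Of 22 receptors and coregulators 10 rose, NR3C2 3.31-fold and NCOA1 2.57-fold, and ESRRA and GRHL2 fell (median 0.30, camera adjusted p = 0.00524, and adjusted p = 0.272 with an estimated correlation). No list kept its call in this comparison when the correlation was estimated. Lists given without a second count had the same count adjusted over the list alone, here and in the next paragraphs on DCC against FBS.

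Cell cycle and ribosome genes fell in DCC. All 36 mitosis genes fell (median log2 change -1.60, camera adjusted p = 1.21e-16, and adjusted p = 0.293 with an estimated correlation), NDC80, a kinetochore component, 4.81-fold and ANLN, anillin, 4.69-fold. Of 44 DNA replication genes 41 fell, 42 adjusted over the list alone, and 0 rose (median -1.65, camera adjusted p = 7.05e-18, and adjusted p = 0.0715 with an estimated correlation). DTL, a substrate adaptor of the CUL4 ligase, was 8.21-fold, CDC45 7.25-fold and E2F2 7.05-fold lower. All 23 ribosome biogenesis genes fell (median -0.82, camera adjusted p = 1.49e-09, and adjusted p = 0.219 with an estimated correlation), MYC 3.54-fold, NOP16 2.65-fold and NOLC1 2.24-fold. Of 25 ribosomal protein genes 13 fell, 15 adjusted over the list alone, and 0 rose (median -0.30, camera adjusted p = 0.00365, and adjusted p = 0.364 with an estimated correlation), a call lost with quantile normalisation (adjusted p = 0.143). In oxidative phosphorylation 8 of 23 fell, ATP5F1B, an ATP synthase subunit, by 0.48 on the log2 scale, and 2 rose, NDUFB3 among them (median -0.16, camera adjusted p = 0.0984, and 0.00945 with normexp).

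Cholesterol, fatty acid, glycolysis, secretory pathway and glycosylation genes fell in DCC. Of 24 cholesterol genes 16 fell and 2 rose, HSD17B7 and SC5D (median log2 change -0.33, camera adjusted p = 0.0242, and adjusted p = 0.361 with an estimated correlation), SREBF2, a sterol-sensing transcription factor, lower by 0.91 and EBP, a sterol isomerase, by 0.86 on the log2 scale, a call lost with quantile normalisation (adjusted p = 0.0586). Of 18 fatty acid genes 10 fell and GPAM rose (median -0.48, camera adjusted p = 0.00524, and adjusted p = 0.219 with an estimated correlation), ELOVL7 8.64-fold lower. Of 22 glycolysis genes 13 fell and ENO2 rose (median -0.51, camera adjusted p = 0.00524, and adjusted p = 0.364 with an estimated correlation), HK2, hexokinase 2, 4.36-fold and LDHA, lactate dehydrogenase A, 2.95-fold lower. Of 32 secretory pathway genes 22 fell, 24 adjusted over the list alone (median -0.45, camera adjusted p = 4.47e-06, and adjusted p = 0.114 with an estimated correlation), DDIT3, a stress transcription factor, 2.97-fold. Of 24 glycosylation genes 14 fell and 0 rose, 17 and 1 adjusted over the list alone (median -0.44, camera adjusted p = 7.87e-05, and adjusted p = 0.293 with an estimated correlation), ST6GALNAC1 14.9-fold lower. Polyamine and prostate secretory genes did not pass, with 6 lower and 2 higher of 14, MSMB 5.26-fold lower and ACP3, prostatic acid phosphatase, 4.56-fold higher (median -0.13, camera adjusted p = 0.273). Steroid metabolism did not pass either, with 6 lower and 4 higher of 17 and AKR1C3, which makes testosterone from androstenedione, 7.34-fold higher (median -0.11, or 0.02 with normexp, but mean 0.67 and test direction up, camera adjusted p = 0.914).

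WNT and BMP genes rose in DCC, with 11 higher and 2 lower of 17, FZD5 and BMPR1B (median log2 change 0.89, camera adjusted p = 0.000528, and adjusted p = 0.219 with an estimated correlation). ID1, a target of BMP signals, was 34.5-fold, ID3 12.9-fold and LEF1, a WNT effector, 7.75-fold higher. Of 10 measured neuroendocrine markers 5 rose and SCG3 fell (median 0.84, camera adjusted p = 0.0273, and adjusted p = 0.293 with an estimated correlation), SCGN, secretagogin, at least 4.47-fold, DDC 5.52-fold and TUBB3, a neuronal tubulin, 4.13-fold higher. That call was lost without DCC 1 (adjusted p = 0.0618). HOX and neural crest factors had 4 higher and 1 lower of 8, HOXC9 5.31-fold higher (median 0.63, camera adjusted p = 0.0871, and 0.047 without FBS 1 or 0.0326 without DCC 1). Growth factor genes had 6 higher, 7 adjusted over the list alone, and 7 lower of 18, IRS1, an insulin receptor substrate, 6.07-fold lower and IGFBP3 4.11-fold higher (median -0.09, camera adjusted p = 0.848).

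Stress and immune lists and the other cell type lists did not pass between DCC and FBS. Heat shock and oxidative stress genes had 11 lower and 3 higher of 20, SLC7A11, the cystine transporter, 3.80-fold lower (median log2 change -0.38, camera adjusted p = 0.0628, and 0.00414 with normexp or 0.028 without FBS 2). The p53 targets had 11 lower and 4 higher of 20, 6 higher adjusted over the list alone, PMAIP1, a BH3-only factor, 5.18-fold lower (median -0.39, camera adjusted p = 0.17, and 0.0222 with normexp). Immediate early genes had 4 higher and 4 lower of 20, ATF3 4.80-fold lower (-2.26, other probes from -2.25 to -0.28) and JUN 2.28-fold higher (median -0.12, or 0.03 with normexp, camera adjusted p = 0.742), and apoptosis regulators 4 higher and 3 lower of 18 (median 0.16, camera adjusted p = 0.404). Interferon genes had 8 higher and 5 lower of 26, 11 and 6 adjusted over the list alone (median 0.26, camera adjusted p = 0.141), and NF-kB genes 7 higher and 2 lower of 16, 7 and 3 adjusted over the list alone (median 0.14, camera adjusted p = 0.153). Luminal markers had 5 higher and 8 lower of 18 (median -0.09, or 0.08 with quantile normalisation and 0.07 in the authors' value table, camera adjusted p = 0.581). Epithelial-mesenchymal genes had 2 higher, 3 adjusted over the list alone, and 5 lower of 13, VIM, vimentin, 3.17-fold higher (median -0.07, or 0.05 with normexp, but mean 0.01, camera adjusted p = 0.785). Basal markers had 1 higher and 3 lower of 9 (median -0.45, or 0.05 with normexp, camera adjusted p = 0.236), fibroblast markers 1 higher of 3, COL1A1 (median 0.35, camera adjusted p = 0.466), and leukocyte markers 0 higher and 3 lower of 9, CD14, CD79A and CD3D, 2 adjusted over the list alone (median -0.16, camera adjusted p = 0.282).

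In DCC against FBS limma called 4817 genes higher and 5543 lower, 43.7% of those tested, against 10 and 20 by title, and 1507 and 1393 of them changed at least 2-fold. Counts without the 2 arrays with contradictory labels are not given, since DCC then held 1 array and only the FBS pair gave a spread. Without FBS 2, 3048 were higher and 3041 lower, and without FBS 1, 3379 were lower. Besides slide row, the share of serum (5% against 10%) changed with the steroids in this comparison, and 46.5% of the calls were higher, against 56.8% with normexp, which moved the median over all genes from -0.076 to 0.04.

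Most genes that passed in both comparisons moved in opposite directions with steroid withdrawal and with R1881, among them KLK3, S100P and ANGPT2 (lower, then higher) and OPRK1, UGT2B15 and IL1B (higher, then lower). Of 5543 genes lower in DCC than in FBS, 2356 rose with R1881 (42.5%), and of 4817 higher in DCC, 3119 fell with R1881 (64.7%). These 5475 genes compare with 2458 if the calls were independent lists, while 561 genes were higher in both comparisons (1014 if independent) and 856 lower in both (1485 if independent). By title 0 genes moved in opposite directions, since limma called 0 genes between R1881 and DCC there. Both comparisons share the DCC arrays, which alone pull the changes apart: across genes the log2 changes correlated at -0.56, against -0.499 in simulated unchanged groups, and had a covariance of -0.425 against -0.021, a difference of -0.404. Unchanged groups gave at most 2 genes in opposite directions in 100 simulations. Those simulations held no changed genes, and groups that differ in unrelated ways also give a negative covariance through the shared DCC level. The covariance and the count of opposite changes therefore cannot by themselves show that R1881 reversed the effect of withdrawal. The 2 DCC arrays were not split between the comparisons, so part of the excess may come from them. They also filled slide row 2, and a shift of that slide row, which the simulations left out, would itself give opposite changes. Against FBS, 790 of the 2356 genes raised by R1881 passed above the FBS level, 338 stayed below it and 1228 had no call, and of the 3119 lowered by R1881, 931 passed below the FBS level, 403 stayed above it and 1785 had no call. A further 2070 genes rose and 2369 fell with R1881 without a call between DCC and FBS.

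**Figure D3:**
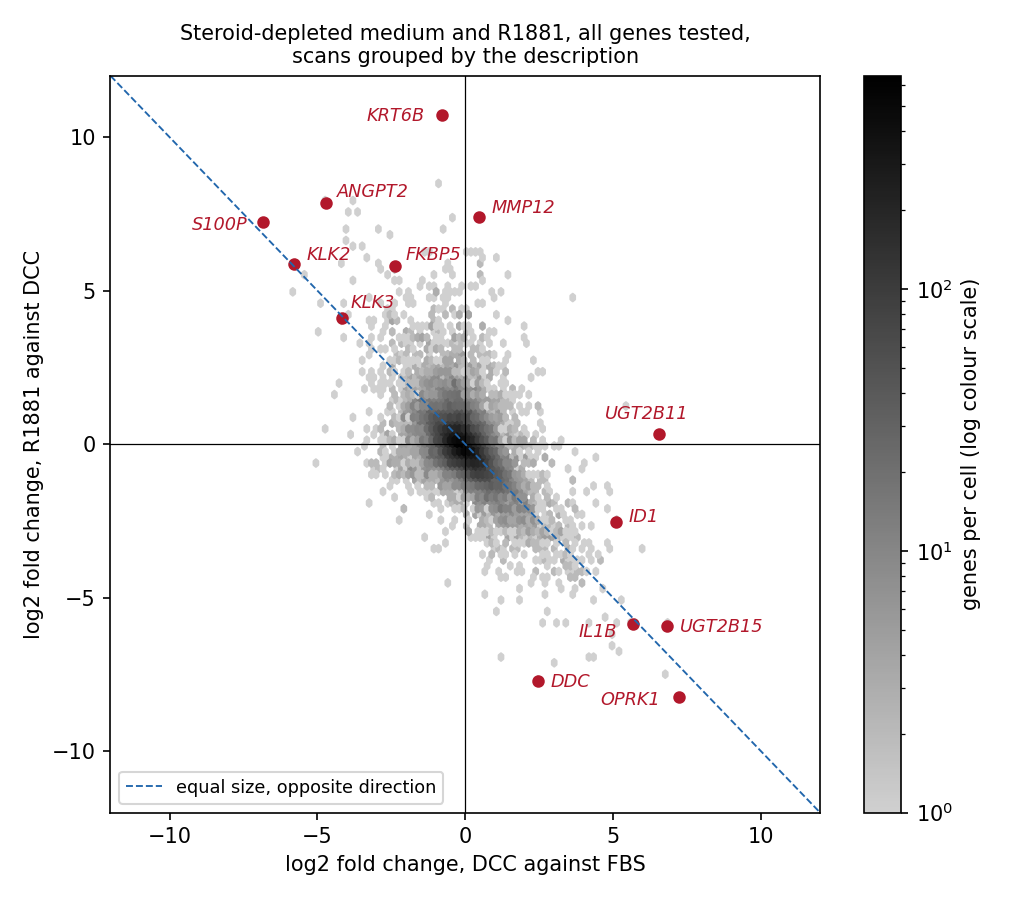
Log2 fold change of all genes tested in DCC against FBS (horizontal axis) and R1881 against DCC (vertical axis), scans grouped by the description, with shading for the number of genes on a log scale and the dashed line for changes of equal size in opposite directions. KLK3 lay at -4.18 and 4.11, OPRK1 at 7.23 and -8.24, and UGT2B11 at 6.55 and 0.33.

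Compared with cells in steroid-containing medium, R1881-treated cells had KLK3, KLK2 and TMPRSS2 without a called difference but other androgen targets higher. The log2 changes were -0.07 ± 0.10 SE for KLK3 (adjusted p = 0.571), 0.09 ± 0.13 for KLK2 (0.577) and 0.22 ± 0.10 for TMPRSS2 (0.14). The other KLK2 probe rose by 1.29 and the mean of both by 0.69 (adjusted p = 0.00617), and TMPRSS2 passed with the trend and robust options (0.0472). FKBP5 was 10.8-fold higher (3.43 ± 0.09, adjusted p = 7.64e-05). KRT6B was 978-fold, UGT2B7, a glucuronosyltransferase, 367-fold, KRT6C at least 205-fold, MMP12 at least 118-fold and CHST2, a sulfotransferase, at least 105-fold higher. H3C15 was 51.0-fold, DDC 37.8-fold, CDH26, a cadherin, 37.0-fold, MMP16 at least 33.9-fold and OR51E1, an olfactory receptor expressed in prostate, 23.8-fold lower (-4.57, other probe -3.90).

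Of the 26 canonical androgen-induced genes 16 were higher with R1881 than in FBS and 2 lower, STEAP2 and TRPM8 (median log2 change 0.92, camera adjusted p = 5.55e-07, and adjusted p = 0.175 with an estimated correlation), HPGD 17.3-fold higher and ORM1 raised by 4.39. The broad androgen response had 75 higher and 3 lower of 101, PA2G4, VAPA and ZMIZ1, and 77 and 4 adjusted over the list alone (median 1.07, camera adjusted p = 1.03e-21), PTPN21, a phosphatase, 22.2-fold higher. It was the 1 list of this comparison to keep its call with an estimated correlation (adjusted p = 0.0243). Androgen-repressed genes had 10 lower and 3 higher of 13, UGT2B15, MET and AKR1C3 (median -1.07, camera adjusted p = 0.00623, and adjusted p = 0.294 with an estimated correlation), CAMK2N1 20.6-fold lower and PEG3 lowered by 4.39 on the log2 scale (other probe -1.20). Receptors and coregulators had 11 lower and 2 higher of 22, NCOA4 and PIAS1 (median -0.43, camera adjusted p = 0.075). Lists given without a second count had the same count adjusted over the list alone, here and in the next paragraphs on R1881 against FBS.

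Cell cycle genes were lower with R1881 than in FBS. Of 36 mitosis genes 35 fell (median log2 change -2.42, camera adjusted p = 1.27e-16, and adjusted p = 0.222 with an estimated correlation), TOP2A 10.3-fold and CENPA, a centromeric histone, 8.97-fold. All 44 DNA replication genes fell (median -1.62, camera adjusted p = 9.34e-18, and adjusted p = 0.074 with an estimated correlation), DTL 12.9-fold and MCM10 9.89-fold. Of 25 ribosomal protein genes 24 fell, 25 adjusted over the list alone (median -0.63, camera adjusted p = 3e-07, and adjusted p = 0.194 with an estimated correlation), and of 23 biogenesis genes 21 fell (median -0.80, camera adjusted p = 9.09e-08, and adjusted p = 0.175 with an estimated correlation), with MYC 7.16-fold and FBL, fibrillarin, 2.96-fold lower. Oxidative phosphorylation had 5 higher and 2 lower of 23, 4 and 1 adjusted over the list alone (median -0.04 but mean 0.03 and test direction up, camera adjusted p = 0.654). The p53 targets had 13 lower, 14 adjusted over the list alone, and 4 higher of 20, CDKN2B at least 22.1-fold and CDKN1C 4.14-fold higher (median -0.52, camera adjusted p = 0.057, and 0.033 with quantile normalisation or 0.0453 without FBS 2).

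Metabolic and secretory lists were mostly higher with R1881 than in FBS. Cholesterol genes had 20 higher, 21 adjusted over the list alone, and TM7SF2 lower of 24 (median log2 change 1.23, camera adjusted p = 9.06e-11, and adjusted p = 0.102 with an estimated correlation), HMGCS1 5.86-fold and FDFT1, squalene synthase, 3.75-fold higher. Fatty acid genes had 13 higher and 2 lower of 18 (median 0.81, camera adjusted p = 3.37e-06, and adjusted p = 0.102 with an estimated correlation), FASN, fatty acid synthase, 2.89-fold higher. Polyamine and secretory genes had 8 higher and SRM lower of 14 (median 1.31, camera adjusted p = 0.000227, and adjusted p = 0.13 with an estimated correlation), SMS 8.07-fold higher. Steroid metabolism had 10 higher and 2 lower of 17, 3 lower adjusted over the list alone (median 0.92, camera adjusted p = 0.000575, and adjusted p = 0.175 with an estimated correlation), UGT2B11 118-fold and AKR1C1 7.68-fold higher. Glycosylation genes had 11 higher, 14 adjusted over the list alone, and GALNT7 lower of 24 (median 0.28, camera adjusted p = 1.86e-05, and adjusted p = 0.208 with an estimated correlation). Secretory pathway genes had 11 higher and 5 lower of 32 (median 0.11, camera adjusted p = 0.0709, and 0.0441 with normexp), and glycolysis genes 4 higher and 8 lower of 22, 9 lower adjusted over the list alone (median -0.20 but mean 0.01, camera adjusted p = 0.677), PFKFB2 6.36-fold higher and PDK1, a kinase that inhibits pyruvate dehydrogenase, 2.32-fold lower.

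Of 16 NF-kB and inflammatory genes 11, and of 26 interferon genes 13, were higher with R1881 than in both other media. Against FBS alone, NF-kB and inflammatory genes had 11 higher and TNFAIP2 lower of 16 (median log2 change 2.31, camera adjusted p = 1.12e-05, and adjusted p = 0.102 with an estimated correlation), CXCL10 at least 94.7-fold, TNFAIP3, an NF-kB feedback inhibitor, 23.7-fold and TNF at least 19.6-fold higher. Interferon genes had 17 higher, 18 adjusted over the list alone, and 3 lower of 26, MX1, OAS3 and USP18 (median 0.65, camera adjusted p = 5.34e-06, and adjusted p = 0.175 with an estimated correlation), IFIT1 4.91-fold higher. Immediate early genes had 9 higher and 2 lower of 20, MYC and SPRY2 (median 0.34, camera adjusted p = 0.00236, and adjusted p = 0.222 with an estimated correlation), DUSP5 11.4-fold higher. Heat shock genes had 7 higher, 8 adjusted over the list alone, and 5 lower of 20, HMOX1 7.32-fold higher (median 0.25, camera adjusted p = 0.0301, and adjusted p = 0.222 with an estimated correlation), a call lost without FBS 2 (adjusted p = 0.0842). Apoptosis regulators had 7 higher and 4 lower of 18, 5 lower adjusted over the list alone, BIRC3 16.9-fold higher (median 0.16, camera adjusted p = 0.13). Leukocyte markers, measured beside them, had CD68 higher (4.24 on the log2 scale) and CD3D lower (-0.58) of 9, CD68 alone adjusted over the list alone (median -0.26 but mean 0.29 and test direction up, camera adjusted p = 0.934).

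Growth factor genes had 9 higher and 2 lower of 18, IRS1 and FGFR1 (median log2 change 0.29, camera adjusted p = 0.0115, and adjusted p = 0.294 with an estimated correlation), IGFBP3 37.5-fold higher. WNT and BMP genes had 8 higher and SMAD6 lower of 17 (median 0.26, camera adjusted p = 0.00269, and adjusted p = 0.194 with an estimated correlation), ID2 21.7-fold and ID3 10.5-fold higher. Luminal markers had 9 higher and 2 lower of 18, HOXB13 and FOLH1, with 3 lower adjusted over the list alone (median 0.28, camera adjusted p = 0.0189, and adjusted p = 0.347 with an estimated correlation), KRT8 7.33-fold higher (2.87, other probe 3.60). Basal markers had 4 higher and ITGA6 lower of 9, LAMB3 38.9-fold higher (median 0.21, camera adjusted p = 0.171). Epithelial-mesenchymal genes had 4 higher and SNAI1 lower of 13, SNAI2 11.7-fold (above background on 1 of 2 FBS arrays) and VIM 8.34-fold higher (median -0.06, or 0.02 with quantile normalisation and 0.05 in the authors' value table, but mean 0.40 and test direction up, camera adjusted p = 0.182). Neuroendocrine markers had TUBB3 higher (5.00-fold) and DDC and SCG3 lower of 10 (median -0.06, or 0.02 with quantile normalisation and 0.07 in the authors' value table, mean -0.18 but test direction up, camera adjusted p = 0.753). HOX and neural crest factors had SOX9 higher (3.94-fold) and ETV1 lower (1.75-fold) of 8 (median -0.13 but mean 0.01, camera adjusted p = 0.905), and ACTA2 (3.34-fold) and COL1A1 (1.38-fold) of the 3 fibroblast markers were higher (median 0.46, camera adjusted p = 0.11, and 0.0496 without FBS 1).

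In R1881 against FBS, which lay together in slide row 1, limma called 4452 genes higher and 6121 lower, 44.6% of those tested, against 1 and 0 by title, and 1549 and 1591 of them changed at least 2-fold. Counts without the 2 arrays with contradictory labels are not given, since R1881 then held 1 array and only the FBS pair gave a spread. The number lower was 3892 without R1881 1, 4036 without FBS 1 and 3936 without FBS 2. The share of serum (5% against 10%) changed with the medium here too.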

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

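Grouped by title, the planned setting, limma called 0 higher and 0 lower for R1881 vs DCC, 10 and 20 for DCC vs FBS, and 1 and 0 for R1881 vs FBS, with 0 genes in opposite directions. Grouped by the description field, the counts were 4987 and 6344, 4817 and 5543, and 4452 and 6121, with 5475 genes in opposite directions. All 30 calls of DCC vs FBS and the 1 call of R1881 vs FBS by title kept their direction. FKBP5 went to 5.80 (R1881 vs DCC) and -2.37 (DCC vs FBS). Without the 2 arrays with contradictory labels the counts were 3698 and 3935, 3507 and 4777, and 3246 and 4561, with 3959 in opposite directions, and FKBP5 was at 5.75 and -2.30. The authors' value table, whose columns go with the title, gave 5574 and 5760, 4895 and 5789, and 4830 and 5506, with 5662 in opposite directions, and FKBP5 at 5.87 and -2.46.

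With the title grouping kept, calls for R1881 vs DCC stayed at 0 in every other setting. For DCC vs FBS (higher and lower) and R1881 vs FBS (higher and lower) the counts were 21 and 49, and 17 and 41 with normexp background, 23 and 50, and 7 and 14 with quantile normalization, 32 and 76, and 26 and 56 with probes above background on all 6 arrays, and 27 and 63, and 16 and 32 with trend and robust eBayes. No filter gave 0 and 0 for DCC vs FBS (limma, 3972 at an unadjusted p under 0.05) and 0 higher for R1881 vs FBS (3427). Every probe kept gave 0 and 0, and 0. Only the 2 groups compared gave 0 and 0 (3756 unadjusted) and 0 (3434). A replicate block gave 0 and 0 (2334) and 0 (1965). The slide row as a block gave 3621 and 5223 for DCC vs FBS and 3555 and 4538 for R1881 vs FBS, and 0 for R1881 vs DCC. Slide row 2 holds the 2 scans described as DCC, so that block takes up their difference from the others. Both comparisons with FBS then in effect set the scans described as R1881 against FBS. Each array left out in turn gave 0 and 0 for DCC vs FBS and 0 higher for R1881 vs FBS, with 1112 to 3756 genes at an unadjusted p under 0.05 in these 2 comparisons.

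By title the broad androgen response passed camera in DCC vs FBS, where it rose, and the canonical and androgen-repressed lists passed in no comparison. By description each of these lists passed camera in every comparison. However, the canonical genes, some of which the broad list also held, had helped to choose that grouping. Canonical androgen-induced genes passed at adjusted p = 8.02e-16 (R1881 vs DCC), 7.85e-12 (DCC vs FBS) and 5.55e-07 (R1881 vs FBS), with adjusted p = 0.0932, 0.193 and 0.175 with an estimated correlation. Androgen-repressed genes passed at 3.68e-07, 0.00889 and 0.00623, with adjusted p = 0.156, 0.364 and 0.294 with an estimated correlation. The broad androgen response passed at 1.02e-27, 7.21e-08 (opposite to the title grouping) and 1.03e-21, with adjusted p = 0.0169, 0.0715 and 0.0243 with an estimated correlation. The calls that follow were made at the preset correlation alone. The slide row block by title gave canonical genes at 1.41e-06 (DCC vs FBS) and 2.92e-07 (R1881 vs FBS) and repressed genes at 0.0104 and 0.00392. With that block both comparisons in effect set scans described as R1881 against FBS. The first is thus no comparison of DCC with FBS and cannot be set beside the one by description. With each array left out in turn, by title, camera adjusted p, in either direction, ranged from 3.42e-08 to 0.735 for canonical, 0.000644 to 0.73 for repressed and 2.66e-15 to 0.73 for broad genes in R1881 vs DCC, from 0.00423 to 0.938 for canonical and 2.54e-10 to 0.186 for broad genes in DCC vs FBS, and from 0.00198 to 0.794 for canonical and 2.22e-10 to 0.0821 for broad genes in R1881 vs FBS.

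Settings combined with the description grouping were added after the data had been seen. There, 1784 and 2017 genes (R1881 vs DCC), 1507 and 1393 (DCC vs FBS), and 1549 and 1591 (R1881 vs FBS) had a log2 change of at least 1, and 1461 were in opposite directions. With each array left out, DCC vs FBS ranged from 3048 to 4331 higher and 3041 to 5296 lower, R1881 vs FBS from 3892 to 6525 lower, and opposite directions from 3534 to 5083. Leaving out the 2 arrays with contradictory labels is not counted here, since DCC and R1881 then held 1 array each. A replicate block gave 4791 and 6136, 4580 and 5216, and 4257 and 5914, with 5108 in opposite directions. The slide row could not be fitted as a block. Of 11331 calls for R1881 vs DCC, 10306 were kept in direction with quantile normalization, 10599 with normexp (3 opposite), 10186 in the authors' value table and 10827 with a gene's probes averaged (12 opposite).

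By description, named gene results were the same in 1122 comparisons with an alternative, stronger in 2 and weaker in 0. The label check genes had helped to choose this grouping, and the other named genes were selected for the largest changes on these same arrays. Few of them could lose a call, so that tally does not measure how robust the other calls are. List results were the same in 913, stronger in 50, weaker in 59, of which 52 came from the estimated correlation, and reversed in 1: fry gave neuroendocrine markers 0.00327 for R1881 vs FBS in the other direction. By title, named gene results were the same in 396, stronger in 23, weaker in 236 and reversed in 6, and list results the same in 235, stronger in 14, weaker in 32 and reversed in 18. Samples of different groups share only a replicate number: differences between replicates 1 and 2 correlated across genes at 0.021, 0.063 and 0.093 by description and at -0.012, 0.04 and -0.848 by title.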

Other observations

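Of the tests below, all but the comparison of the androgen-induced genes between the 2 doubtful scans were chosen after results had been seen, as were the gene families.

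Protocadherin beta genes, which encode cell adhesion molecules of neurons and lie in 1 cluster, rose together in DCC, with 14 of 14 measured higher than in FBS (median log2 change 2.24, range 1.07 to 3.77, camera adjusted p = 5.67e-08, and adjusted p = 0.671 with an estimated correlation). All 14 fell with R1881 (median -2.18, camera adjusted p = 5.95e-06, and adjusted p = 0.748 with an estimated correlation), PCDHB10 (-4.11) and PCDHB16 (-2.91) among them, and 2 of 14 differed between R1881 and FBS (median 0.05, camera adjusted p = 0.693). Near-identical sequences leave open which member each probe measured. HOXC genes, developmental factors of another cluster, had 6 of 7 higher in DCC (median 1.82, camera adjusted p = 0.00122, and adjusted p = 0.671 with an estimated correlation) and 7 of 7 lower with R1881 (median -1.98, camera adjusted p = 0.00615, and adjusted p = 0.748 with an estimated correlation), HOXC9 by 2.42. Metallothioneins, which bind zinc and copper, went the other way, with 8 of 10 lower in DCC and MT1F higher (median -1.06, camera adjusted p = 0.0165, and adjusted p = 0.722 with an estimated correlation) and 8 of 10 higher with R1881 (median 1.24, camera adjusted p = 0.000674, and adjusted p = 0.748 with an estimated correlation), MT1G by 1.98. Their probes may also detect one another's transcripts.

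UGT2B genes, which inactivate androgens, divided by medium. UGT2B15 rose by 6.84 in DCC and fell by 5.91 with R1881, while UGT2B11 rose by 6.55 in DCC and had no call with R1881 (0.33, adjusted p = 0.0958), and UGT2B7 rose by 3.68 and then by 4.84. Of 8 measured UGT genes 7 were higher with R1881 than in FBS (median log2 change 3.66, camera adjusted p = 0.000168, and adjusted p = 0.7 with an estimated correlation). Small nucleolar RNA host genes, which belong to the growth-regulated transcripts of ribosome production, had 12 of 16 lower and 1 higher in DCC (median -0.62, camera adjusted p = 0.0068, and adjusted p = 0.671 with an estimated correlation) and 13 lower and 1 higher with R1881 than in FBS (median -1.17, camera adjusted p = 0.000818, and adjusted p = 0.7 with an estimated correlation). MMP7, matrilysin, was 32.8-fold higher with R1881 than in DCC, and CCL5, a chemokine, at least 15.4-fold. Among 366 families of genes that share a symbol prefix, 15, 33 and 36 passed for R1881 against DCC, DCC against FBS and R1881 against FBS, and 0 with an estimated correlation. That last test has 3 residual degrees of freedom, so almost no family could pass it.

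The 2 arrays with contradictory labels could carry a right description or scans exchanged between records, and the 2 readings give each scan the same group. In the scan titled R1881 1, the 26 androgen-induced genes lay at a median of -3.71 against the scan titled DCC 1, which fits both readings. Each scan matched the other record's column of the value table at 0.9995 or more. That fits an exchange of the scans or, with a right description, of those columns. Neither result tells the 2 readings apart. A right title with each scan in its own record is excluded, since 3.85% of the 26 genes were higher in the scan titled R1881 1.

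Of the genes tested 47.8% differed between R1881 and DCC, while both DCC arrays filled slide row 2. A shift of slide row 2 cannot be separated from the medium, since the design joins them in each comparison with DCC. The 10 spike-in controls moved by a median absolute log2 difference of 0.14 between R1881 and DCC (range -0.62 to 0.16). Called genes changed by a median of 0.74, but they were selected for their change and the controls were not. The controls were scaled to the same percentile, so a shift common to a whole array cancels in them. Within slide row 1 their range was no narrower (-0.91 to 0.15, R1881 against FBS). They therefore do not decide on a row shift. A shift limited to other probes stays open. Within slide row 1, R1881 also differed from FBS in the same direction at 56.7% of the 11331 calls, against 22.7% if the calls were independent, but the shared R1881 arrays raise that share. Quantile normalisation kept 10306 of the 11331 calls, so most do not depend on the choice between these 2 scalings. Both scalings bring the arrays to a common level, so this test cannot exclude an error they share. With normexp 4720 genes were higher and 9369 lower, against 4987 and 6344.

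Of 16 NF-kB and inflammatory genes 11 were higher with R1881 than in both other media, though both calls were lost with an estimated correlation (adjusted p = 0.0932 and 0.102), IL1B and NFKB1 were lower than in DCC, and TNFAIP2 was lower than in FBS. RNA of leukocytes is not excluded, but the cultures were of the LNCaP line and the leukocyte markers as a set argue against it. Their median log2 change between R1881 and FBS was -0.26. Of 9 markers 1, the macrophage marker CD68, was higher with R1881 than in both other media (4.24 against FBS). CD14 (-0.42), CD79A (-0.26) and CD3D (-0.58) did not rise against FBS. A difference between slide rows is excluded for the rise against FBS, a median of 2.31 within slide row 1, and stays open for the rise against DCC, a median of 1.92. A direct action of R1881 on these genes could not be told from a secondary one with 1 time point.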
